A study of Mus musculus with 19 samples.

How the data were processed

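The series holds 19 RNA sequencing libraries from whole perigonadal adipose tissue of C57BL/6 mice in 2 models of weight gain. The models are a 60% high-fat diet (HFD) and Ensure, each sampled at peak weight while fed or after 24 hours without feeding. Groups were taken from the labels: HFD fed (n = 4), HFD fasted (n = 4), Ensure fed (n = 6) and Ensure fasted (n = 5). Libraries are named by group and by the number in their title. The labels do not say in so many words that each library is a separate animal, so p-values measure the spread between these samples.

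Per the labels' protocols, RNA was extracted with an RNeasy kit, poly-adenylated RNA was selected, libraries were made with a TruSeq RNA kit, and sequencing was done on a HiSeq2000. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.1 and HTSeq 0.6.1 were used with the mouse build mm9; their settings, including strand, are not given in the sources used here. The authors deposited, for each library, whole-number read counts per gene symbol, not normalized. Genes that overlap on opposite strands, and near-identical copies such as ribosomal proteins or the mast cell tryptases, can share or lose reads in such counts, so their values are uncertain. The reference given for this work is a later build, and no coordinates are printed.

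Each file listed 24348 genes plus HTSeq's summary lines, which were kept out of library sizes and tests. Reads outside genes made up 13.01 to 17.32% of a library, ambiguous reads 0.70 to 0.89% and reads that were not unique 20.67 to 27.7%. Counts assigned to genes were 12.82 to 22.55 M per library (median 20.23 M), so that 3 counts, used as the floor for a gene at 0, correspond to 0.133 to 0.234 counts per M counts (CPM). Intervals and floors of this kind cover counting error only. No genes were left out other than by the filter; 3202 had 0 counts in all 19 libraries. The 37 pairs of libraries within a group differed by a chi-square of 7.04 to 288 per gene, far above sampling noise, so no library was counted as a repeat of another.

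The main test was edgeR's quasi-likelihood F test (glmQLFit, glmQLFTest; edgeR 4.0.16, R 4.3.3) in 1 fit of all 19 libraries with 4 groups, TMM scaling and genes kept by filterByExpr at a minimum count of 10, which left 16015 genes. Calls are at an adjusted p (Benjamini-Hochberg) under 0.05. Standard errors of log2 fold changes were taken as the log2 fold change divided by the square root of its F statistic. The contrasts were fasted against fed within each diet, the difference between those 2 responses, and Ensure against HFD among fed and among fasted libraries. Levels are TMM-scaled CPM, as mean ± SD.

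Gene lists for adipose pathways, fasting and other cell types (43 lists) were tested with limma 3.58.1 camera on voom values at an inter-gene correlation of 0.01, adjusted over lists within a contrast. The 40 lists with at least 5 tested genes were used, and 99.5% of the listed symbols were present in the files. The same lists were tested with an estimated correlation and with fry, which passed, for a shift in 1 direction and for changes in either, 0 and 3 of the 8 lists that camera called with HFD, 8 and 8 of 11 with Ensure, 1 and 1 of 8 in the difference, 6 and 6 of 13 between fed and 2 and 8 of 15 between fasted diets, and calls of members were also counted adjusted over the list alone. Of the 55 list calls at the preset correlation, 2 held with an estimated correlation: the glucocorticoid-responsive list in the difference of responses and between the diets among fasted libraries. Both contrasts use the same fasted libraries, so these 2 calls are not separate results.

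Tests, alternatives, lists and the rule for naming genes were fixed before the data were examined. The rule took, per contrast, up to 10 genes higher and 10 lower with the largest fold among called genes whose groups did not overlap and whose mean was at least 1 CPM, passing over predicted names. It added up to 4 members of each list by smallest p and 12 genes fixed in advance. Every gene of the first part and the 12 fixed genes are named; which list members are named in the text was chosen after their values were seen. Some list members are not reported here.

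The test was checked on simulated counts with 200 changed genes per contrast. For 2-fold changes it called 45% (HFD), 47% (Ensure), 25% (difference), 48% (diets, fed) and 49% (diets, fasted), and for 4-fold changes 84, 81, 68, 80 and 80%. False calls made up 1.06 to 6.52% of the calls. The simulated genes varied independently, without tract reads, epithelial cells or lane effects. These shares can therefore be too favourable for the real libraries, where another split of the fasted libraries called 5296 genes. Each simulation ran on 15835 to 15851 genes.

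Alternatives were DESeq2 size factors, library size alone, no filter, a stricter filter, DESeq2 1.42.0, limma voom with sample quality weights, sequencing lane as a term, the 2 compared groups alone and leaving out each library in turn. After the data were seen, 4 more were added: leaving out Ensure fasted 2 and 5, leaving out the 5 libraries with most reproductive tract marker reads, leaving out the 8 libraries that are among these 5 or have the epithelial gene Cdh16 above 20 CPM, and adding the levels of those markers as 2 terms. The labels place all HFD libraries in sequencing lane 7; Ensure fed libraries lie in lanes 5 (1 library), 6 (4) and 7 (1), and Ensure fasted libraries in lanes 5 (4) and 6 (1). Diet and lane therefore overlap almost completely. The numbers in the titles run from 1 to 18 for Ensure and from 21 to 28 for HFD libraries. Diet thus follows this numbering completely, which a lane term does not cover. Within Ensure, feeding state and lane overlap in large part.

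Single libraries were compared with their group by Dixon's ratio, whose 95% values (0.829 for 4 libraries, 0.710 for 5 and 0.627 for 6) were computed from simulated normal samples.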

Results

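Gene expression in perigonadal fat, the depot around the epididymis in male mice, was measured in 19 libraries: 4 HFD fed, 4 HFD fasted, 6 Ensure fed and 5 Ensure fasted. HFD is a 60% high-fat diet and Ensure the food of the other model of weight gain. Titles read ALO or ALOneg for HFD libraries and OIO or OIOneg for Ensure libraries. Diet below stands for the whole model. Fasted animals had gone 24 hours without food after reaching peak weight. Each library held 12.82 to 22.55 M counts in genes. Ensure fasted 2 was the shallowest, at 12.82 M, so its low counts carry more counting error.

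All libraries were male by expression: Xist was at most 0.619 CPM and 4 Y-linked genes summed to 208 to 362 CPM. The first principal component of the 500 most variable genes held 71.8% of the variance and the second 14.3%, and each of the 4 groups had libraries on both sides of the first. Ensure fasted 2, HFD fasted 24 and Ensure fasted 5 lay furthest to its negative side, where the epithelial genes Pax8, Cdh16, Mmp7 and Dcdc2a had high weights. Cdh16 was at 38.4 to 60.4 CPM in HFD fed 21, HFD fasted 24 and 26, Ensure fed 16 and Ensure fasted 2 and 5, and at most 12.7 CPM in the others. The 15-gene epididymis and testis list summed to 212.9 to 11192 CPM in 5 libraries (HFD fasted 24, Ensure fed 10 and 12, Ensure fasted 2 and 5) and to at most 87.5 CPM in the other 14. The 4 sperm-cell genes Prm1, Prm2, Tnp1 and Tnp2 reached 669 CPM in Ensure fasted 2 and 280 CPM in HFD fasted 24, while the epididymis genes reached 11064 CPM in Ensure fasted 5, of which 9444 CPM was Crisp1.

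**Figure D1:**
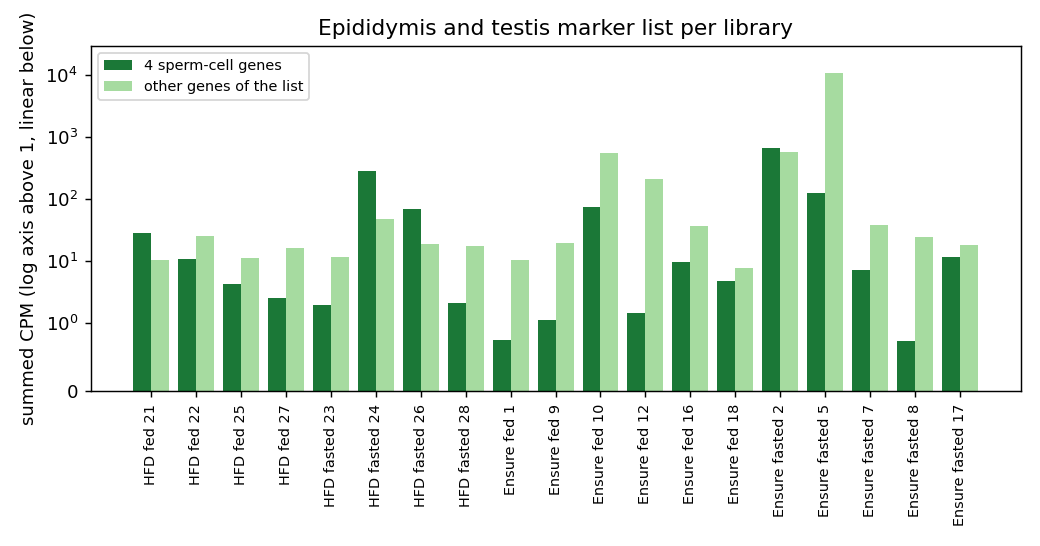
Summed CPM of the 4 sperm-cell genes (dark bars) and of the other genes of the epididymis and testis list (light bars) in each of the 19 libraries, on an axis that is linear below 1 and logarithmic above. The highest bar is the epididymis genes of Ensure fasted 5 at 11064 CPM; HFD fasted 24, Ensure fed 10 and 12 and Ensure fasted 2 are the other libraries whose list sums to over 100 CPM.

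The first question was what 24 hours without food changed in fat of mice fed HFD. Called lower were 3 of 16 triglyceride, 5 of 22 cholesterol and 1 of 20 fatty acid synthesis genes, and these lists did not pass with an estimated correlation (adjusted p = 0.908 to 0.956). Fry, which tests a list without comparing it with other genes, gave adjusted p = 0.116 to 0.324 for a shift in 1 direction and 0.00641 to 0.0164 for changes in either. Dgat2, which makes triglyceride from diglyceride, went from 2732 ± 781 to 820 ± 142 CPM (SD, n = 4 and 4; log2 fold change -1.74 ± 0.28 SE, adjusted p = 0.00782). Pnpla3, a lipid-droplet protein induced by feeding, went from 377 ± 85.9 to 107 ± 25.6 CPM (log2 fold change -1.82 ± 0.26, adjusted p = 0.00373). Klf15, a transcription factor of fuel metabolism, fell (log2 fold change -1.38 ± 0.18, adjusted p = 0.00277), and Igfbp3, an insulin-like growth factor binding protein, rose from 36.7 ± 6.95 to 84.4 ± 21.2 CPM. In all, 30 genes were higher and 165 lower of 16015 tested, and the groups did not overlap for 191 of the 195. Chance gives 2.86% for a gene not chosen by its difference. Called genes were chosen on these same libraries, so the share is no test of the calls.

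The named genes that rose after fasting with HFD were Acta1 (12.6 ± 3.87 to 54.0 ± 16.8 CPM), Wisp2 (log2 fold change 2.02), Dusp9 (1.84), Slc22a14 (1.58), Mmp11 (1.40), Hilpda (1.31), Igfbp3 (1.20), Plk3 (1.11), Piezo2 (1.09) and the lipid-droplet gene Plin5 (1.08). Those that fell were Asb12 (-2.38), Mogat2 (-2.29), the desaturase Scd2 (-2.04), Grid1 (-2.00), Trabd2b (-1.90), Pnpla3 (-1.82), Dgat2 (-1.74), Odf3l1 (-1.72), Paqr9 (-1.67) and Tuba1a (-1.65). Their adjusted p-values were 0.00373 to 0.0482. After fasting, Asb12 was at 0.0548 CPM in HFD fasted 28 and 0.254 to 0.304 CPM in the other HFD fasted libraries. These levels are near the floor, so the fold of Asb12 is uncertain. Acta1 is a skeletal muscle gene and the only called member of the 9 tested muscle markers.

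Of 22 tested cholesterol synthesis genes, 5 fell and none rose with HFD (8 fell adjusted over the list alone), among them Mvk (-0.88), Pmvk (-0.92), Lss (-1.02) and Idi1 (-1.10). Camera gave this list adjusted p = 5.16e-07, and adjusted p = 0.908 with an estimated correlation. Of 20 fatty acid synthesis genes 1 fell (8 adjusted over the list alone; camera adjusted p = 1.85e-05, adjusted p = 0.908 with an estimated correlation); Fasn itself, fatty acid synthase, stood at a log2 fold change of -1.54 ± 0.37 with adjusted p = 0.0518. Of 16 triglyceride synthesis genes 3 fell, including Agpat2 (-1.15) (4 adjusted over the list alone). Camera gave this list adjusted p = 3.99e-05, and adjusted p = 0.956 with an estimated correlation. Of 18 genes of branched-chain amino acid breakdown 1 fell, Mccc2 at -0.74 (6 adjusted over the list alone). By camera the list had adjusted p = 1.85e-05, and adjusted p = 0.956 with an estimated correlation. Camera also called oxidative phosphorylation (47 genes, adjusted p = 0.00103) and adipocyte markers (16 genes, adjusted p = 0.014) lower, and ribosomal proteins (38 genes, adjusted p = 0.00167) and B cell markers (12 genes, adjusted p = 0.00994) higher, with 0 members called by edgeR over all genes or adjusted over the list alone. Each had adjusted p = 0.956 with an estimated correlation. Beside these, the 14 lipid-associated macrophage markers had a median log2 fold change of 1.14 with HFD and 0 called members; camera gave adjusted p = 0.0608, and 7.91e-05 without the 5 libraries rich in tract markers, and adjusted p = 0.956 with an estimated correlation.

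Among the 16 glucocorticoid-responsive genes with HFD, Klf15 and Pik3r1 (-0.84) fell and Sgk1 rose (0.77); adjusted over the list alone 1 rose and 3 fell. The hexokinase Hk2 fell (-0.82) and the clock gene Clock fell (-0.41). Of the fixed genes, Pdk4 had a log2 fold change of 1.58 ± 0.38 (adjusted p = 0.0518), Lep -1.18 ± 0.37 (0.138), Srebf1 -0.53 (0.107), Lipe -0.37 (0.467), Pck1 0.30 (0.784), Angptl4 -0.27 (0.61), Adipoq -0.26 (0.681), Scd1 -0.16 (0.84), Ucp1 -0.07 (0.988), Pnpla2 0.04 (0.959) and Fkbp5 0.01 (0.984).

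The HFD count rests on few libraries: edgeR called 85, 72, 23 and 100 genes without HFD fed 21, 22, 25 and 27, and 59, 63, 141 and 63 without HFD fasted 23, 24, 26 and 28. It called 62 with lane as a term, 143 without the 5 libraries rich in tract markers, 910 (545 higher, 365 lower) without these and the 3 others rich in Cdh16, and 1 in a fit of the 2 groups alone. Of the 31 named calls, Trabd2b, Pnpla3, Dgat2, Hk2, Klf15 and Pik3r1 remained in every omission. The others ended in part: 17, 17, 25 and 13 ended without HFD fed 21, 22, 25 and 27, and 20, 18, 9 and 20 without HFD fasted 23, 24, 26 and 28, at adjusted p up to 0.216. Lss had a log2 fold change of -0.68 without HFD fed 25. With lane as a term 14 of the 31 named calls remained, 20 without the 5 libraries and 24 without the 8; those that ended with lane were Acta1, Slc22a14, Mmp11, Piezo2, Plin5, Asb12, Mogat2, Odf3l1, Paqr9, Tuba1a, Agpat2, Pmvk, Lss, Idi1, Mccc2, Sgk1 and Clock, at adjusted p up to 0.0879. All HFD libraries share lane 7, so the lane term left HFD fold changes as they were (median shift 0). These calls therefore ended without a change of fold. Whether the estimated spread or the fewer degrees of freedom ended them was not tested.

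The same question for Ensure gave a larger set of called genes when all libraries were in the fit. Called lower were 14 of 22 cholesterol, 10 of 20 fatty acid and 8 of 16 triglyceride synthesis genes, on lists that did not pass with an estimated correlation (adjusted p = 0.204 to 0.727) and passed with fry for a shift in 1 direction (adjusted p = 1.1e-04, 8.13e-04 and 0.0306). Pdk4, which blocks pyruvate entry into the citric acid cycle, was higher. Fasn went from 9196 ± 1735 to 2832 ± 1285 CPM (SD, n = 6 and 5; log2 fold change -1.70 ± 0.32 SE, adjusted p = 0.0018), and Acly, which makes cytosolic acetyl-CoA, from 1151 ± 232 to 310 ± 56.5 CPM (-1.89 ± 0.20, adjusted p = 2.38e-05). Pdk4 rose from 81.1 ± 26.1 to 477 ± 216 CPM (2.56 ± 0.33, adjusted p = 9.38e-05). In all 1690 genes were higher and 1565 lower, and the groups did not overlap for 2014 of the 3255. Chance gives 0.433% for a gene not chosen by its difference, so this is no test of the called genes.

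The named genes that rose most with Ensure were Ank1 (log2 fold change 4.16), Sbk2 (3.77), Dusp13 (3.66), Ankmy1 (3.62), Dazl (3.40), Vnn1 (3.22), Rdh9 (3.09), Prss55 (2.83), Nupr1l (2.81) and the glucose transporter Slc2a3 (2.71). Dazl and Prss55 are germ cell genes, and the sperm-cell gene sum was 669 CPM in Ensure fasted 2 and 127 CPM in Ensure fasted 5, against at most 74.3 CPM in Ensure fed libraries. Those that fell most were Asb12 (-3.61), Lppr4 (-3.46), Mstn (-3.17), Grid1 (-3.11), Lrtm1 (-2.93), Dio2 (-2.87), Tuba1a (-2.57), Otop1 (-2.47), Trabd2b (-2.46) and Paqr9 (-2.43). Adjusted p-values in these 20 were 1.63e-05 to 0.0458. Without Ensure fasted 2, log2 fold changes were 2.30 for Dusp13, 2.12 for Dazl and 1.59 for Prss55, and Ank1 was at 0.92 without Ensure fasted 5.

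Of the cholesterol synthesis genes, 14 of 22 fell with Ensure and none rose (15 adjusted over the list alone), among them Pmvk (-1.50), Nsdhl (-1.48), Lss (-1.36) and Mvk (-1.07). By camera the list had adjusted p = 1.18e-11, and adjusted p = 0.204 with an estimated correlation. Of the fatty acid synthesis genes 10 of 20 fell and none rose, including Scd2 (-2.20) and Acss2 (-1.89), and adjusted over the list alone 13 fell and 3 rose. The camera test gave adjusted p = 9.77e-07, and adjusted p = 0.319 with an estimated correlation. Of the triglyceride synthesis genes 8 of 16 fell, including Agpat2 (-2.00) and Dgat2 (-1.84), and 1 rose, Pck1 (1.53), with the same counts adjusted over the list alone. For this list camera returned adjusted p = 0.00106, and adjusted p = 0.727 with an estimated correlation. Of 47 oxidative phosphorylation genes 13 fell (19 adjusted over the list alone), including Uqcrc2 (-0.57), Atp5g3 (-0.51) and Cyc1 (-0.45), by smaller steps. Tested as a list with camera, they had adjusted p = 1.09e-09, and adjusted p = 0.63 with an estimated correlation.

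Glycolysis genes fell in 6 of 15 with Ensure, such as Pfkp (-0.71), and Hk1 rose (0.88; 0.57 without Ensure fasted 2); adjusted over the list alone 7 fell and 1 rose. Camera gave this list adjusted p = 0.0135, and adjusted p = 0.319 with an estimated correlation. Of 14 thermogenic genes 4 fell, Dio2 and Otop1 among them, also adjusted over the list alone. By camera the list had adjusted p = 0.0282, and adjusted p = 0.342 with an estimated correlation. Branched-chain amino acid breakdown had 1 gene up and 1 down of 18, and 1 up and 5 down adjusted over the list alone (camera lower, adjusted p = 0.0252, adjusted p = 0.939 with an estimated correlation).

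Of the 16 glucocorticoid-responsive genes, 9 rose and 3 fell with Ensure (11 and 3 adjusted over the list alone): Fkbp5, a glucocorticoid receptor co-chaperone, went from 74.6 ± 9.00 to 188 ± 70.6 CPM (1.34 ± 0.22, adjusted p = 5.94e-04), and Mt1 (1.19), Per1 (0.80) and Sgk1 (0.77) rose. Camera gave adjusted p = 0.0135 and adjusted p = 0.184 with an estimated correlation. Igfbp3 (1.22) and Plin5 (0.91) rose, and the adipokine Lep (-1.34, adjusted p = 0.00821), Igf1 (-1.04), Srebf1 (-0.56) and Clock (-0.55) fell. The Lep call ended with lane as a term (-1.23, adjusted p = 0.111) and without the 5 libraries (-1.01, adjusted p = 0.0716), and the Plin5 call with lane (0.88, adjusted p = 0.0986). Of the other fixed genes, Ucp1 was at -2.14 (adjusted p = 0.303), Pnpla2 at 0.51 (0.14), Lipe at -0.24 (0.405), Adipoq at 0.13 (0.727), Angptl4 at -0.10 (0.759) and Scd1 at 0.03 (0.949).

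Smooth muscle markers rose in 8 of 10 with Ensure (9 adjusted over the list alone), such as Synpo2 (1.13) and Cnn1 (4.88). The camera test gave adjusted p = 0.0296, and adjusted p = 0.83 with an estimated correlation. The smooth muscle gene Myh11 was at 4029 CPM in Ensure fasted 5, 47.1 to 146 CPM in the other fasted and 72.7 to 141 CPM in the fed Ensure libraries. The Synpo2 call ended with lane as a term (1.17, adjusted p = 0.0679) and without the 5 libraries (1.18, adjusted p = 0.0698). Cnn1 rested on Ensure fasted 5, whose epididymis gene sum was 11064 CPM, and was at 0.41 without that library, adjusted p = 0.652. Immediate-early genes rose in 5 of 18 (6 adjusted over the list alone; camera adjusted p = 0.0252, adjusted p = 0.564 with an estimated correlation), including the heat-shock gene Hspa1a at 1.84 and at 0.80 without Ensure fasted 5. Of 24 interferon-responsive genes 2 rose, Irf9 (0.43; 0.24 without Ensure fasted 5) and Oasl2 (0.78), and 0 adjusted over the list alone. The camera test gave adjusted p = 0.0135, and adjusted p = 0.939 with an estimated correlation. These 2 of 24 interferon-responsive genes are no more than the share over all genes, where 1690 of 16015 rose.

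Higher calls with Ensure were 904, 1016 and 888 without Ensure fed 9, 12 and 18 and 980 without Ensure fasted 5. With lane as a term edgeR called 260 genes higher and 500 lower, 503 and 642 without the 5 libraries rich in tract markers, and 312 and 460 without the 8. Within lane 5 (4 fasted, 1 fed) 99.9% of the 3255 called genes moved the same way and within lane 6 (1 fasted, 4 fed) 96.7%, on libraries that also chose the genes. Over all genes, Pearson's r with the full fold changes was 0.846 in lane 5 and 0.237 in lane 6. Of the 52 named calls 46 remained in every omission and Dazl, Prss55, Mstn, Cnn1, Irf9 and Oasl2 did not: 4 ended without Ensure fed 12, 16 or 18, 3 without Ensure fed 1, Ensure fed 10 or Ensure fasted 5, 2 without Ensure fed 9, Ensure fasted 2 or 17, and 1 without Ensure fasted 8, at adjusted p up to 0.652. With lane as a term 34 of the 52 remained, 36 without the 5 libraries and 30 without the 8. Those that ended with lane were Cnn1, Dazl, Ank1, Prss55, Slc2a3, Hspa1a, Irf9, Hk1, Nupr1l, Ankmy1, Dusp13, Lep, Mstn, Plin5, Pck1, Dio2, Synpo2 and Oasl2, at adjusted p from 0.612 (Cnn1) to 0.0532 (Oasl2). Those that ended without the 5 libraries were Ankmy1, Dazl, Prss55, Nupr1l, Mstn, Dio2, Otop1, Lep, Sgk1, Per1, Synpo2, Cnn1, Hk1, Irf9, Oasl2 and Hspa1a.

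**Figure D2:**
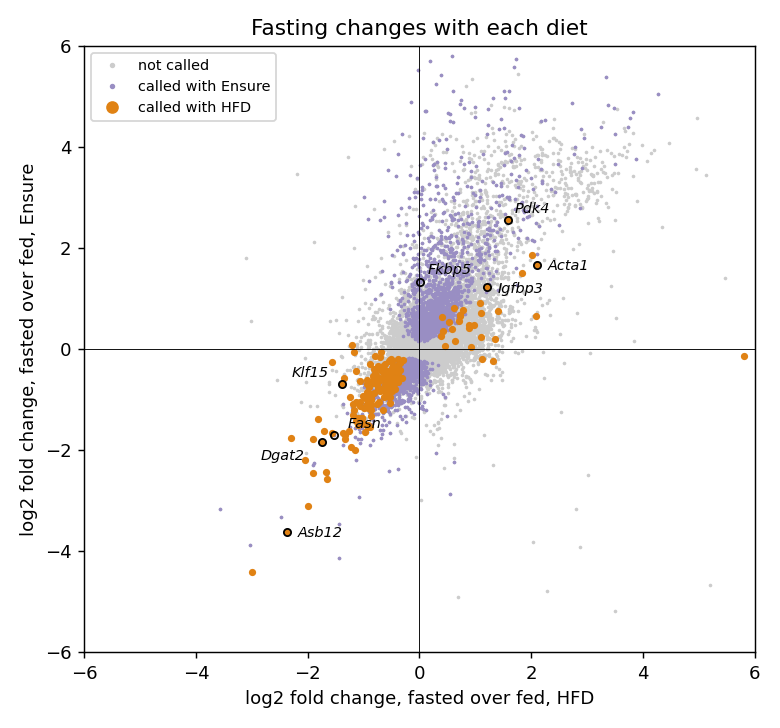
Log2 fold change of fasted over fed libraries for each of 16015 genes with HFD (horizontal axis) and with Ensure (vertical axis); grey points were not called, violet points were called with Ensure and orange points with HFD, and 2 genes lie outside the axes. Of the 195 orange points, 191 have the same sign with both diets.

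The responses to fasting were then set side by side. Across the 16015 genes, which are not independent replicates, log2 fold changes with HFD and with Ensure had Pearson's r = 0.669 and Spearman's rho = 0.644, with no library shared between the 2 contrasts. Of the 30 genes higher with HFD 19 were higher with Ensure (3.17 for independent lists), and of the 165 lower genes 148 were lower with Ensure (16.12 for independent lists). Both sets of calls came from 1 fit that shares its estimates of spread. Independent lists are thus a loose reference and no test. Without the 5 libraries rich in tract markers, r was 0.168 and rho 0.297 over all genes. Over genes of at least 10 CPM they were 0.461 and 0.462, against 0.6129 and 0.6325 with all libraries. With lane as a term they were 0.561 and 0.521 over all genes.

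The test of the difference between the 2 fasting responses called 0 genes by edgeR, with 1234 genes at an unadjusted p under 0.05 where 801 would be so by chance, and a lowest adjusted p of 0.302. DESeq2 called 33 higher and 37 lower and voom with quality weights 876 and 294. At the level of lists, glucocorticoid-responsive genes were higher in the Ensure response (camera adjusted p = 1.68e-06, adjusted p = 0.00121 with an estimated correlation; 5 of 16 adjusted over the list alone, 0 over all genes). Fkbp5 had a difference of 1.32 ± 0.34 (SE, adjusted p = 0.383), Zbtb16 1.29 ± 0.42 (0.525), Tsc22d3 0.90 ± 0.30 (0.534) and Klf15 0.69 ± 0.24 (0.542). Cholesterol synthesis (camera adjusted p = 4.35e-06, adjusted p = 0.973 with an estimated correlation), oxidative phosphorylation (8.94e-06, adjusted p = 0.973 with an estimated correlation) and fatty acid synthesis (0.0132, adjusted p = 0.973 with an estimated correlation) were lower in the Ensure response, with 0 members called and 0 adjusted over the list alone. Acly had a difference of -1.01 ± 0.29 (adjusted p = 0.461) and Insig1 -0.95 ± 0.36 (0.567). The other fixed genes had differences of Ucp1 -2.08 (adjusted p = 0.862), Pck1 1.23 (0.688), Pdk4 0.98 (0.665), Pnpla2 0.47 (0.818), Adipoq 0.39 (0.843), Scd1 0.19 (0.952), Angptl4 0.17 (0.927), Fasn -0.16 (0.957), Lep -0.15 (0.959), Lipe 0.13 (0.948) and Srebf1 -0.03 (0.988).

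**Figure D3:**
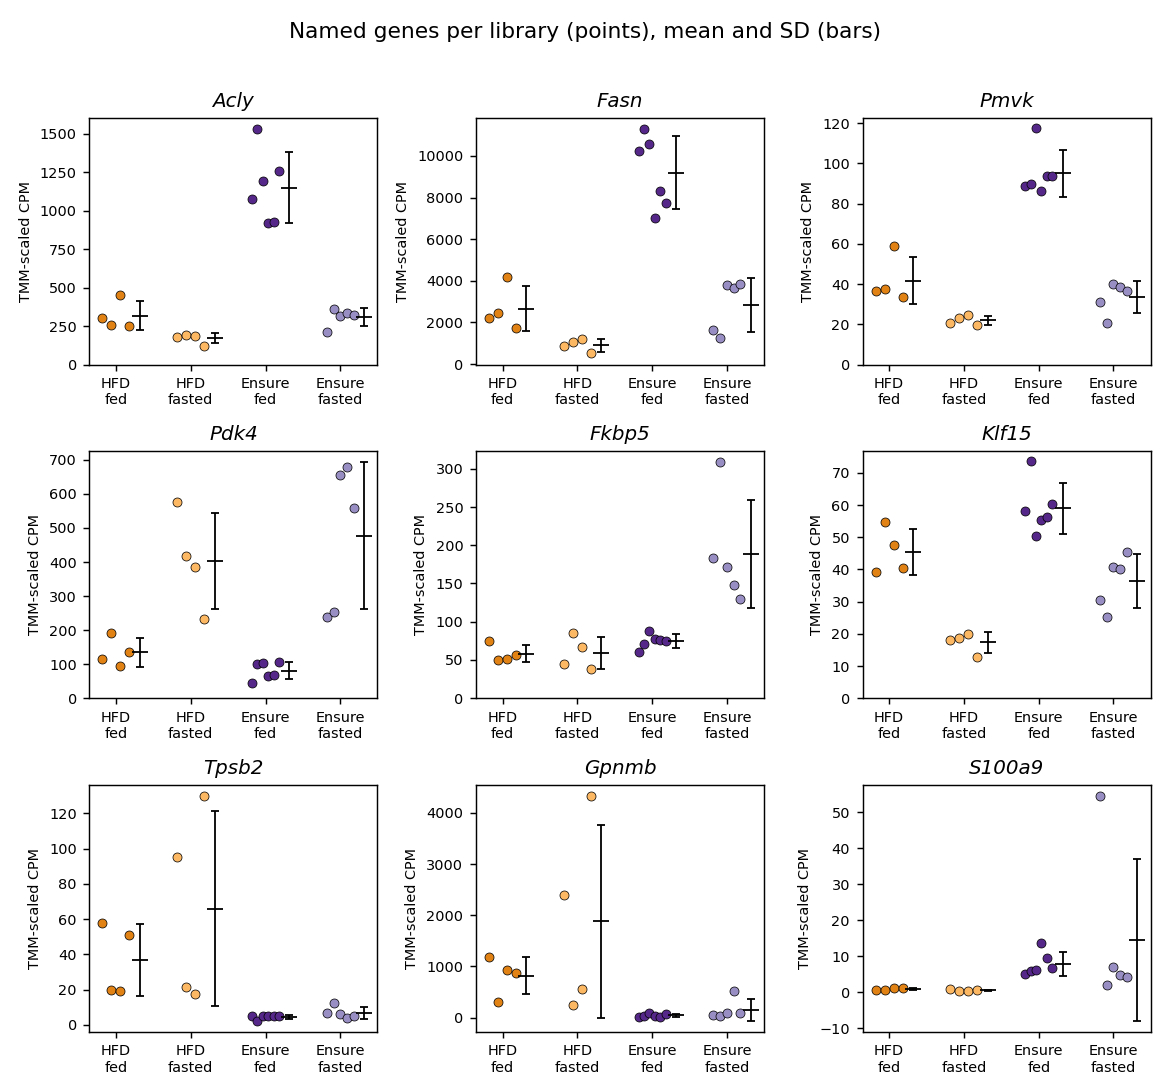
TMM-scaled CPM of 9 named genes in each library (points), with the mean and SD of each group (bars beside the points). Fkbp5 averages 188 CPM in Ensure fasted libraries and 58.3 to 74.6 CPM in the other groups, and Acly and Fasn are highest in Ensure fed libraries.

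At peak weight, Ensure was compared with HFD. Called higher with Ensure were 9 of 20 fatty acid, 6 of 22 cholesterol and 2 of 16 triglyceride synthesis genes, and lower 6 of 8 mast cell and 6 of 14 lipid-associated macrophage markers, on lists that did not pass with an estimated correlation (adjusted p = 0.141 to 0.804). With fry for a shift in 1 direction the fatty acid (adjusted p = 0.00102), cholesterol (0.00877) and mast cell lists (0.0447) passed, and the triglyceride (0.356) and macrophage lists (0.0885) did not. Acly was at 1151 ± 232 against 317 ± 94.1 CPM (SD, n = 6 and 4; log2 fold change 1.86 ± 0.21 SE, adjusted p = 3e-04) and Fasn at 9196 ± 1735 against 2652 ± 1076 CPM (1.79 ± 0.35, adjusted p = 0.00922). Tpsb2, a mast cell tryptase, was at 4.62 ± 1.09 against 36.8 ± 20.3 CPM (-2.99 ± 0.52, adjusted p = 0.00432), and Gpnmb, a glycoprotein of lipid-laden macrophages, at 41.9 ± 29.6 against 822 ± 364 CPM (-4.29 ± 0.87, adjusted p = 0.0101). In all 335 genes were higher and 347 lower with Ensure, and the groups did not overlap for 582 of 682. Chance gives 0.952% for a gene not chosen by its difference, so this is no test of the called genes. All 4 HFD fed libraries lay in lane 7 and 5 of the 6 Ensure fed libraries in other lanes; with lane as a term edgeR called 2 genes higher and 0 lower, with Serpina3b the 1 named call left.

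Named genes higher in fed Ensure libraries were the chemokine Cxcl13 (log2 fold change 4.77), Fpr1 (4.51), Serpina3b (3.61), Irg1 (3.57), Cxcr2 (3.27), Angptl7 (3.27), S100a9 (3.24), Fbn2 (3.13), Dio2 (3.02) and Ccl8 (2.79). Named genes lower were Gpr50 (-7.08), Sbk2 (-4.51), Gpnmb (-4.29), Myh15 (-4.04), Mmp12 (-3.82), Atp6v0d2 (-3.77), Tm4sf19 (-3.72), Tph1 (-3.70), Mrgprb2 (-3.53) and Tpsab1 (-3.44), at adjusted p-values of 3.68e-05 to 0.0449 over the 20. Fpr1 was at 2.99 without Ensure fed 9.

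Of the fatty acid synthesis genes 9 of 20 were higher among fed libraries (14 adjusted over the list alone), with Elovl6 (2.68) and Acss2 (1.75). For this list camera returned adjusted p = 8.64e-13, and adjusted p = 0.141 with an estimated correlation. Of the cholesterol synthesis genes 6 of 22 were higher (12 adjusted over the list alone), with Cyp51 (1.29) and Pmvk (1.19). Tested as a list with camera, they had adjusted p = 3.92e-11, and adjusted p = 0.173 with an estimated correlation. Camera called higher, each with fewer called members, oxidative phosphorylation (3 of 47, 8 adjusted over the list alone; Atp5g3 0.46; adjusted p = 5.96e-11, adjusted p = 0.532 with an estimated correlation). It also called glycolysis (1 of 15, 3 adjusted over the list alone; adjusted p = 0.00115, adjusted p = 0.173 with an estimated correlation) and triglyceride synthesis (2 of 16, 5 higher and 1 lower adjusted over the list alone; Agpat2 1.12; adjusted p = 0.00197, adjusted p = 0.804 with an estimated correlation).

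Extracellular matrix genes were higher in 6 of 27 (15 higher and 3 lower adjusted over the list alone), with Eln (2.06), Col3a1 (1.33) and Col1a1 (1.05). Camera gave this list adjusted p = 4.92e-07, and adjusted p = 0.58 with an estimated correlation. Of the immune markers, 6 of 8 mast cell genes were lower (6 adjusted over the list alone), with Mcpt4 (-3.15), Cma1 (-2.73) and Cpa3 (-2.46). By camera the list had adjusted p = 1.08e-04, and adjusted p = 0.483 with an estimated correlation. Lipid-associated macrophage markers were lower in 6 of 14 (11 adjusted over the list alone), with Itgax (-2.56). The camera test gave adjusted p = 4.48e-07, and adjusted p = 0.551 with an estimated correlation. Neutrophil markers were higher in 3 of 9 (6 adjusted over the list alone), S100a9, Cxcr2 and Mmp9 (2.14). For this list camera returned adjusted p = 2.38e-05, and adjusted p = 0.301 with an estimated correlation. The T cell gene Cd4 was higher (2.40). Camera also called lysosome genes lower (1 of 26, 6 adjusted over the list alone; adjusted p = 1.31e-04, adjusted p = 0.88 with an estimated correlation). It called, with 0 members called by edgeR over all genes or adjusted over the list alone, immediate-early genes lower (adjusted p = 0.00437, adjusted p = 0.405 with an estimated correlation) and cell cycle (0.00203, adjusted p = 0.997 with an estimated correlation) and interferon-responsive genes higher (6.94e-05, adjusted p = 0.88 with an estimated correlation).

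Of the other fixed genes among fed libraries, Ucp1 was at 1.74 (adjusted p = 0.636), Pck1 -1.39 (0.0882), Pdk4 -0.73 (0.248), Lep 0.58 (0.395), Adipoq -0.58 (0.204), Srebf1 0.37 (0.157), Fkbp5 0.36 (0.469), Pnpla2 -0.25 (0.7), Angptl4 0.23 (0.667), Scd1 -0.12 (0.917) and Lipe -0.02 (0.977). Omitting 1 library left 339, 301 and 239 calls without HFD fed 21, 22 and 27 and 419, 426 and 408 without Ensure fed 1, 10 and 12, and the fit of the 2 groups alone made 1443 higher and 1490 lower calls. Of 39 named calls 23 remained in every omission. Of the rest 12, 13, 5 and 13 ended without HFD fed 21, 22, 25 and 27, and 9, 7, 6, 9, 6 and 1 without Ensure fed 1, 9, 10, 12, 16 and 18, at adjusted p up to 0.143. Without the 5 libraries 35 of the 39 remained, and 23 without the 8, where 115 genes were called higher and 98 lower.

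After fasting, Fasn was higher in Ensure than in HFD libraries (2832 ± 1285 against 914 ± 307 CPM, SD, n = 5 and 4; log2 fold change 1.63 ± 0.36 SE, adjusted p = 0.0232) and the mast cell gene Tpsb2 lower (6.70 ± 3.30 against 66.0 ± 55.5 CPM, -3.29 ± 0.55, adjusted p = 0.00532). Fkbp5 was at 188 ± 70.6 against 58.8 ± 21.2 CPM (1.68 ± 0.25, adjusted p = 0.00296). In all 261 genes were higher and 191 lower with Ensure; scaling by library size alone gave 215 higher and 308 lower. The groups did not overlap for 326 of the 452. Chance gives 1.59% for a gene not chosen by its difference, so this is no test of the called genes. Of 100 splits of the fasted libraries, 8 gave as many calls, the real one included, so chance is not excluded. No lane holds both fasted groups, and with lane as a term, which borrows from the fed libraries, edgeR called 0 genes (495 at an unadjusted p under 0.05, lowest adjusted p 0.341). Without that term DESeq2 called 773 higher and 570 lower and voom with quality weights 2073 and 1345.

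Named genes higher in fasted Ensure libraries were S100a9 (log2 fold change 4.98), Svs5 (3.83), Trp63 (3.38), Il22ra2 (3.30), Cyp2b10 (3.10), Elovl6 (3.08), Adamts8 (2.88), Serpina3b (2.82) and Masp1 (2.56), and Ngp, for which no fold is given because it had 0 counts in all 4 HFD fasted libraries. Svs5 is a seminal vesicle gene. Named genes lower were Eef1a2 (-4.53), Tpsab1 (-4.32), Gpr50 (-4.17), Mrgprx2 (-3.76), Pramef12 (-3.64), Trdn (-3.54), Mrgprb1 (-3.50), Mrgprb2 (-3.43), Pianp (-3.41) and Mcpt4 (-3.32). Adjusted p-values were 5.25e-04 to 0.05. S100a9 was at 3.28 without Ensure fasted 2, Svs5 at 2.07 without Ensure fasted 17, Trp63 at 1.92 and Adamts8 at 1.63 without Ensure fasted 5, and Eef1a2 at -2.69 without HFD fasted 28.

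Glucocorticoid-responsive genes were higher in 4 of 16 among fasted libraries (6 adjusted over the list alone): Fkbp5, Klf15 (1.06), Tsc22d3 (1.05) and Pik3r1 (0.78). Tested as a list with camera, they had adjusted p = 3.02e-06, and adjusted p = 0.00268 with an estimated correlation. The same fasted libraries enter the difference of responses, so the results for this list in both contrasts are not separate. Fatty acid synthesis genes were higher in 4 of 20 (11 adjusted over the list alone), with Acly at 0.85. Camera gave this list adjusted p = 6.19e-08, and adjusted p = 0.345 with an estimated correlation. Camera also called triglyceride synthesis higher (1 of 16, 6 adjusted over the list alone; adjusted p = 0.0199, adjusted p = 0.929 with an estimated correlation). Cholesterol synthesis was called higher (adjusted p = 0.0476, adjusted p = 0.929 with an estimated correlation), with 0 members higher and 1 lower of 22 (1 and 1 adjusted over the list alone). Stress genes of protein folding were higher in 3 of 19, with Hspa5 (0.65) and Pdia4 (0.50) (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0476, adjusted p = 0.345 with an estimated correlation); their median log2 fold change was 0.14 and their mean -0.03.

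Extracellular matrix genes were higher in 8 of 27 (16 higher and 1 lower adjusted over the list alone), with Eln (2.01) and Col1a1 (1.25). By camera the list had adjusted p = 1.65e-09, and adjusted p = 0.345 with an estimated correlation. Interferon-responsive genes were higher in 3 of 24 (16 adjusted over the list alone): Irf7 (2.09), Ifit1 (1.86) and Ifi44 (1.78). The camera test gave adjusted p = 9.68e-12, and adjusted p = 0.345 with an estimated correlation. Smooth muscle markers were higher in 1 of 10 (8 adjusted over the list alone), Mylk at 2.09 and at 1.00 without Ensure fasted 5, the library with 11064 CPM of epididymis genes. For this list camera returned adjusted p = 0.0107, and adjusted p = 0.722 with an estimated correlation. Lysosome genes had 1 higher and 1 lower, Ctsk at -2.80, of 26 (1 higher and 8 lower adjusted over the list alone). For this list camera returned adjusted p = 4.5e-04, and adjusted p = 0.929 with an estimated correlation. Ribosomal proteins were called lower by camera alone (0 members by edgeR; adjusted p = 9.93e-04, adjusted p = 0.929 with an estimated correlation).

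Among immune markers after fasting, 6 of 8 mast cell genes were lower (6 adjusted over the list alone), with Cma1 (-3.30) and Cpa3 (-2.58), and 6 of 14 lipid-associated macrophage markers (12 adjusted over the list alone), with Mmp12 (-4.79; -2.86 without HFD fasted 28), Itgax (-3.15) and Dcstamp (-2.77). Their camera adjusted p-values were 1.15e-05 and 1.63e-10, each with adjusted p = 0.345 with an estimated correlation. Neutrophil markers were higher in 4 of 9 (7 adjusted over the list alone), with Retnlg (4.62; 2.40 without Ensure fasted 2) and Cxcr2 (2.92). Tested as a list with camera, they had adjusted p = 1.03e-04, and adjusted p = 0.345 with an estimated correlation. B cell markers were lower in 1 of 12, Cd22 at -1.80 (6 adjusted over the list alone; camera adjusted p = 2.04e-05, adjusted p = 0.345 with an estimated correlation), and T cell markers in 0 of 16 (1 higher and 3 lower adjusted over the list alone). Tested as a list with camera, they had adjusted p = 4.85e-05, and adjusted p = 0.345 with an estimated correlation.

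Of the other fixed genes among fasted libraries, Lep was at 0.42 (adjusted p = 0.535), Angptl4 0.40 (0.334), Srebf1 0.34 (0.202), Ucp1 -0.34 (0.922), Pdk4 0.25 (0.745), Pnpla2 0.22 (0.694), Adipoq -0.20 (0.717), Pck1 -0.15 (0.883), Lipe 0.11 (0.818) and Scd1 0.08 (0.919). Omitting 1 library left 209, 767 and 227 calls without HFD fasted 23, 24 and 28 and 694, 231, 696 and 221 without Ensure fasted 5, 7, 8 and 17, and the fit of the 2 groups alone made 1 call. Of 45 named calls 20 remained in every omission. Of the rest 19, 2, 6 and 22 ended without HFD fasted 23, 24, 26 and 28, and 2, 2, 11, 1 and 14 without Ensure fasted 2, 5, 7, 8 and 17, at adjusted p up to 0.139. Without the 5 libraries 40 of the 45 remained, and 40 without the 8, where 667 genes were called higher and 931 lower; with lane 0 remained.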

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

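The tests of reproductive tract reads, of epithelial cells and of lane for the Ensure count, and of fasting for the tract transcripts, were chosen after the results were seen, as was the log2 scale on which single libraries were compared with their group.

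A library was set apart when its gap to the nearest other library of its group, as a share of the group's range, exceeded Dixon's 95% value. Over 357 groups (125 genes, in the groups of the contrasts that name them, and 5 measures per library), 34 had such a library, where chance gives about 17.9; on linear CPM, the scale looked at first, 57 did. Of the 34, 13 were in Ensure fasted 5, 6 in HFD fasted 28 and 3 in HFD fed 25. HFD fasted 28 had 17.3% of reads outside genes and 27.7% not unique, and Ensure fasted 5 had 26% not unique. In Ensure fasted 5 the values were Scd2 802, Trabd2b 13.7, Paqr9 15.6, Ank1 122, Rdh9 3.85, Trp63 29.5, Adamts8 18.5, Pfkp 53.2, Igf1 136, Cnn1 771, Hspa1a 25.8 and Mylk 1910 CPM. HFD fasted 28 had Asb12 0.0548, Tuba1a 155, Hk2 44.6 and Acly 121 CPM. HFD fed 25 had Odf3l1 9.54, Idi1 7.41 and Sgk1 74.3 CPM. The others were Grid1 6.87 CPM in Ensure fed 16, Prss55 7.56 and Acly 213 CPM in Ensure fasted 2, Atp6v0d2 49.8 CPM in HFD fed 22, Svs5 0.203 CPM in HFD fasted 23 and 16.9 CPM in Ensure fasted 17, Il22ra2 0.174 and Tsc22d3 88.3 CPM in HFD fasted 24, Pianp 8.63 CPM in Ensure fasted 8, Pmvk 118 and Cyp51 130 CPM in Ensure fed 10, and Tpsb2 2.41 CPM in Ensure fed 9. Asb12 in HFD fasted 28 is 1 count, below the floor of 3, and Svs5 in HFD fasted 23 and Il22ra2 in HFD fasted 24 are 4 counts each, so counting error alone can set these 3 apart.

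At the preset correlation camera called the fasting responses different between the diets for 8 lists, of which 1, the glucocorticoid-responsive list, held with an estimated correlation (adjusted p = 0.00121; the other 7 at 0.973 to 0.985): glucocorticoid-responsive (adjusted p = 1.68e-06), cholesterol synthesis (4.35e-06), oxidative phosphorylation (8.94e-06), interferon-responsive (0.0122), fatty acid synthesis (0.0132), B cell (0.0188), smooth muscle (0.0223) and T cell markers (0.0343). With lane as a term the glucocorticoid-responsive, cholesterol synthesis, oxidative phosphorylation and interferon-responsive lists passed and the other 4 ended; without the 5 libraries rich in tract markers oxidative phosphorylation ended as well. Interferon-responsive and smooth muscle genes were higher in the Ensure response and B and T cell markers lower.

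The first pattern weighed is that fasting called 3255 genes with Ensure and 195 with HFD, an excess whose size depends on the method: 4507 and 634 with DESeq2, 5638 and 2974 with voom quality weights, 3602 and 1 in fits of the 2 compared groups alone, and 2307 and 546 without Ensure fasted 2 and 5. Unequal numbers of libraries do not account for it, since the 75 choices of 4 fasted and 4 fed Ensure libraries gave at least 1130 calls. Lane stays open: as a term it left 760 calls (62 with HFD), which met the bound set against it. Lane 5 holds 4 fasted and 1 fed Ensure libraries and lane 6 holds 1 fasted and 4 fed. The adjusted contrast thus leans on 1 library of a feeding state in each lane, too few to decide. Tract reads stay open. Leaving out the 5 richest libraries left 1145 calls (143 with HFD), and tract levels as terms left 3002 (230 with HFD), so an excess remained in both. The omission kept HFD fed 21, HFD fasted 26 and Ensure fed 16, with Cdh16 at 44.8, 52.1 and 42.7 CPM, against 54.6 CPM in the omitted HFD fasted 24. The terms cover the listed tract markers only. Epithelial cells in some libraries are a candidate cause that stays open. Without those 3 libraries as well, edgeR called 772 genes with Ensure and 910 with HFD, and the excess ended. That fit held 2 or 3 libraries per group. Compared with leaving out 5, Ensure calls fell from 1145 and HFD calls rose from 143. HFD fasted kept only numbers 23 and 28, and number 28 was set apart above for its reads outside genes and not unique. Leaving out 8 other libraries was not run, so this omission cannot tell epithelial cells from the choice of libraries left. Larger changes with Ensure stay open too: over genes called with HFD the median ratio of the Ensure to the HFD log2 fold change was 0.998, and over genes called with Ensure the reverse ratio was 0.461, where each choice of genes favours its own diet. Spread within groups was unequal, and whether it bears on the counts was not tested. Pairs of libraries differed by a chi-square per gene of 24.9 to 93.7 in HFD fed and 29.9 to 288 in HFD fasted. With Ensure it was 7.04 to 31.3 in fed and 12.3 to 258 in fasted libraries.

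In other splits of the libraries, 1 of 35 gave as many calls with HFD, the real split (195, highest other 6), and 1 of 100 with Ensure (3255, highest other 1423). Both met the bound set beforehand against chance, but each is the lowest share these splits allow. They argue against chance without excluding it over 5 contrasts, and a fit of the 2 HFD groups alone made 1 call. The real Ensure split also largely follows lanes 5 and 6. For the difference of responses 31 of 100 splits gave as many genes at an unadjusted p under 0.05 as the real 1234 (highest other 4578), so chance is not excluded there.

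The second pattern is the diet difference at peak weight. Lane and diet cannot be told apart here: the 1 Ensure fed library in the HFD lane, number 18, had a median position of 0.907 between the HFD mean (0) and the mean of the other Ensure libraries (1) over 598 genes called without it, against 0.829 to 1.109 for the other 5. That met the bound set beforehand against lane as the cause, but the bound was wrong because a single library excludes nothing. A diet effect could give the lowest position over the 6 libraries, 0.829, and stays a hypothesis. Only the real split of 100 gave as many calls (682, highest other 20), which argues against chance but does not bear on lane. Among fasted libraries 8 of 100 did (452, highest other 5296), so chance is not excluded there. The splits with most calls (5296 and 4166) kept HFD fasted 24 and 26 and Ensure fasted 2 and 5 on 1 side. Of the fasted libraries, these hold the most sperm-cell reads. They also had Cdh16 at 38.4 to 60.4 CPM, against at most 3.16 CPM in the other fasted libraries. Such splits thus follow a structure of the samples.

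The third pattern is the testis and epididymis transcripts. A candidate source is neighbouring tissue taken with the depot. Over the 9 libraries with at least 20 counts of each of the 4 sperm-cell genes, the SD of their log2 ratios was 0.077 times the SD of their level (0.167 against 2.173). A fixed ratio would follow from any source of sperm-cell reads, so it does not single out neighbouring tissue. It does not cover the epididymis genes. Fasting is not required for these transcripts, since the list summed to 640 CPM in Ensure fed 10 and 212.9 CPM in Ensure fed 12. Whether fasting raises their level stays open. Of 9 fasted libraries, 5 lay below the highest fed library of their diet. That met the bound set against fasting but excludes only a rise in every fasted library. Mean log2 CPM was higher after fasting by 1.19 (sperm-cell) and 0.45 (epididymis) with HFD and by 2.33 and 1.87 with Ensure, with SDs of 0.575 to 3.932. Exact permutation tests (2-sided, 4 tests) gave p = 0.543, 0.4, 0.21 and 0.377 (adjusted p = 0.533 to 0.543), on samples too few and too spread to decide. The list holds 15 genes, of which 6 averaged over 1 CPM in the other 14 libraries.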

How the results depend on the processing

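Leaving out libraries for tract reads or Cdh16, and the tract levels as terms, were alternatives chosen after seeing the data; the others were planned. Counts are higher and lower calls in the order HFD, Ensure, difference, diets fed, diets fasted. DESeq2 size factors, no filter and a stricter filter kept each count within 1.5 times the main one; library size alone did so too, except 308 lower among fasted diets. Counts that moved more were, with DESeq2, 162 and 472, none for Ensure, 33 and 37, 902 and 638, 773 and 570; with voom quality weights 1172 and 1802, 2996 and 2642, 876 and 294, 2420 and 3021, 2073 and 1345; with lane 10 and 52 (at unchanged HFD folds), 260 and 500, none for the difference, 2 and 0, 0 and 0. The compared groups alone gave 0 and 1, no move for Ensure, 1443 and 1490, 0 and 1. Without Ensure fasted 2 and 5 they were 81 and 465, 1061 higher, 3 higher, 755 and 665, 816 and 291. Without the 5 libraries they were 18 higher, 503 and 642, none for the difference, none for diets fed, 434 higher. Without the 8 libraries they were 545 and 365, 312 and 460, 1 higher, 115 and 98, 667 and 931, and with tract levels as terms 48 higher, none for Ensure, 1 higher, 609 and 803, 483 and 299. The cause was not tested, apart from fewer libraries in the omissions. The correlation of responses moved to 0.561 and 0.521 (Pearson, Spearman) with lane and to 0.168 and 0.297 without the 5 libraries, and 2 of the 55 list calls held with an estimated correlation (46 with lane, 46 without the 5 libraries).

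Leaving out each library gave 0 to 36 higher and 23 to 105 lower with HFD, 888 to 1868 and 1272 to 1982 with Ensure, 0 to 0 and 0 to 0 for the difference (1234 genes at an unadjusted p under 0.05 in edgeR with all libraries), 130 to 477 and 100 to 401 for fed diets and 100 to 430 and 88 to 481 for fasted diets. Among named genes, signs turned for HFD Fkbp5 (0.01 with all libraries): -0.22 without the 5 libraries, -0.36 without the 8, -0.14 with tract levels, -0.06 and -0.04 without HFD fed 22 and 25, -0.22 and -0.04 without HFD fasted 24 and 26, with a range over omissions of -0.22 to 0.20 (without HFD fasted 28). They turned for the difference in Lep (-0.15): 0.17 without Ensure fasted 2 and 5, 0.0193 without the 5 libraries and 0.0102 without HFD fed 22, with a range over omissions of -0.53 (without HFD fed 25) to 0.0102. No paired analysis was possible because the groups share no replicate numbers. Depth limits genes under about 0.234 CPM, the floor of the shallowest library.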

Other observations

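The lists described here were tested as planned, and no test was added for them. With Ensure, members of lists whose camera test did not pass were also called. Over all 16015 tested genes, 1690 rose and 1565 fell. Of 18 FoxO and insulin-responsive genes 6 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.233), of 18 clock genes 5 rose and 3 fell (7 and 3 adjusted over the list alone; 0.348) and of 19 protein folding and amino acid stress genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; 0.114). Adipocyte markers fell in 2 of 16 with Ensure (2 adjusted over the list alone, 0.0785), near the share over all genes. Macrophage markers fell in 1 of 22 (1 adjusted over the list alone, 0.911), below that share.

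Between the diets at peak weight, clock genes went both ways, with 3 higher and 2 lower of 18 in Ensure libraries (4 and 7 adjusted over the list alone; camera adjusted p = 0.629). Adipose progenitor markers were lower in 3 of 14 (1 higher and 4 lower adjusted over the list alone; 0.424). The general macrophage list had 1 of 22 genes higher (1 higher and 1 lower adjusted over the list alone; 0.992), while 6 of 14 lipid-associated macrophage markers were lower.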
